A study of Caenorhabditis elegans with 7 samples.

How the data were processed

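Sequencing of mRNA compared starved L1 larvae of the Caenorhabditis elegans strain N2 whose parents had fed ad libitum (AL, 3 libraries) or under dietary restriction (DR, 4 libraries). Per the labels, worms were kept at 20 °C on OP50 bacteria, and parents then grew for 96 hr in S-complete liquid with HB101, with 100 µL of culture per embryo. The food amount of DR parents, 3.1, carries another unit in the labels (ml per mL) than in the deposited notes sheet (mg per mL), which also gives that unit for AL parents. Embryos freed by bleaching stayed in S-basal at 1 per µL for 24 hr and the larvae were frozen. RNA was extracted with TRIzol and sand, and libraries were made with a poly(A) selection kit that does not keep the strand, with 12 PCR cycles.

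Per the submitters' processing notes, reads were aligned with Bowtie 1.1.2 and counted with HTSeq, and edgeR was used for the comparison; versions of HTSeq and edgeR were not given. The genome build and annotation release are not given in the sources used here, and no coordinates are printed. The deposited files hold 1 raw count per annotated feature and library, with HTSeq's summary lines at the end. In a deposited workbook the authors give CPM per library and, from an edgeR exact test on genes with CPM above 1 in 3 libraries, log2 fold changes of DR over AL with a p-value and an adjusted p-value. Each raw count divided by the authors' CPM gave 1 constant per library. The authors' CPM table holds 13439 genes and their comparison 13436.

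Counts of 44968 features were read from the deposited files. Names came from Ensembl release 115 for 44439 features, from RefSeq for 4 and from the authors' table for 177, and 348 had no match. Between 22.2% and 24.0% of the reads of a library fell in the summary lines and were left out. Feature totals lay between 16626117 and 22952310 counts per library. Floors cover counting error only, since reads without molecular identifiers are not independent molecules; the floor is 3 counts of a library's total. CPM printed here are scaled by TMM factors.

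Genes were tested in R 4.3.3 with edgeR 4.0.16 (TMM normalisation, filterByExpr with default settings, quasi-likelihood fit with robust estimation, two-sided F-test, DR minus AL), with Benjamini-Hochberg adjustment over the 14867 genes that passed the filter and a threshold of 0.05. The common biological coefficient of variation was 0.162. The 40 gene lists, named in the text with their results, were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry (limma 3.58.1), over lists with at least 5 tested members. List adjusted p-values are Benjamini-Hochberg values over the 40 lists. Members were also adjusted over the list alone. A list score is the mean over members of log2 CPM centred per gene, with a prior count of 2. Scores and library measures were compared by two-sided exact permutation tests over the 35 splits of the libraries, whose smallest p is 0.0286. Gene and list tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

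The rule for named genes was to name every gene past the threshold if there were at most 30. With fewer than 10 passing, the 15 genes with the smallest p are given as values, and 13 of 14 further genes are given whatever their outcome, the remaining gene being left out: daf-2, daf-16, sod-3, mtl-1, hsp-12.6, ins-7, daf-28, vit-2, vit-6, icl-1, fat-7, acs-2 and lgg-1. List members that did not pass, and genes of the authors' table, are examples chosen after their values were seen.

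Alternatives were other normalisations (size factors, upper quartile, library size only), filters on low counts (none, CPM above 1 or above 5 in 3 libraries), DESeq2 1.42.0, limma-voom, the edgeR exact test, a fit without robust estimation, an adjusted p under 0.1, the replicate letters as a block, the file-name prefixes as a covariate or separately, leaving out mitochondrial and the 10 most abundant features, and leaving out each library in turn. Added after seeing the data were the rRNA share as a covariate, leaving out rRNA features, leaving out both DR C and DR D, the submitters' filter with the exact test, and removal of a length trend per library by an offset (lowess, span 0.3). Where a prefix holds a single library of a group, that library is assumed to vary like the other group. The bootstrap interval of a list median resamples its members and covers the spread between them.

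The gene and list tests were tested on simulated data in 5 runs with 200 changed genes each. Of genes changed 1.5-fold 32.2% were called, and of those changed 2-fold, 3-fold and 4-fold 67.6%, 87.7% and 90.8%; 0.0947% of unchanged genes were called. A shift of 0.2 log2 units in the neuropeptide list was called in 5 of 5 runs, and in 3 with an estimated correlation. Over all runs 2 calls fell on other lists. Simulated genes were drawn independently of each other, whereas the real neuropeptide list had an estimated correlation of 0.338. The runs therefore do not show how the list test behaves when genes vary together. Simulated libraries also shared no structure beyond the groups, so the rates for genes hold only for libraries without one. Pairs of libraries were checked for duplicates, and none was found. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 served for tables and figures.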

Results

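Messenger RNA was sequenced from starved first-stage (L1) larvae of the Caenorhabditis elegans wild type N2, grouped by the diet of their parents. The parents grew in liquid culture for 96 hr with the bacterium HB101, either ad libitum (AL) at 25 or under dietary restriction (DR) at 3.1. The deposited notes give both amounts in mg per mL. Their embryos were freed by bleaching, hatched without food and were collected after 24 hr, so that the larvae of both groups had met no food themselves. There were 7 libraries, 3 of AL progeny (A, B and C) and 4 of DR progeny (A, B, C and D), described by the submitters as biological replicates. Counts in annotated features came to 22952310, 16805120 and 20160191 for AL A, B and C, and to 20756804, 20874237, 20134251 and 16626117 for DR A, B, C and D. Of 44968 features, 25575 had at least 1 read in some library and 14867 entered the gene test. A count of 0 in a library allows between 0.131 and 0.180 CPM (counts scaled to the library total), counting error only. Log2 correlations of expression were 0.978 to 0.985 among AL libraries, 0.979 to 0.981 among DR libraries and 0.967 to 0.989 between the groups.

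The comparison of DR with AL progeny asks whether the parents' food supply left a mark on gene expression in offspring that were themselves starved. In DR progeny, the ammonium transporter gene amt-1 (C05E11.4) rose 2.34-fold, from 14.1 ± 1.46 CPM (SD, n = 3) to 33.1 ± 6.57 CPM (SD, n = 4). The pseudogene K02E7.6 rose 1.70-fold, from 75.6 ± 5.55 to 128.7 ± 8.59 CPM. Transcripts of insulin-like peptides and of neuropeptides were higher as groups, by medians of 0.26 and 0.19 on the log2 scale over 21 and 97 tested genes. Genes of autophagy, of the lysosome and of the insulin/IGF signalling pathway were lower as groups, by medians of −0.17, −0.14 and −0.11 over 33, 64 and 25 genes. These group shifts passed a test with a preset correlation between genes, and none passed with an estimated correlation, where the lowest adjusted p was 0.267. The preset test also called lists in every one of the 35 splits of the libraries, with a median of 14 lists.

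Both amt-1 (log2 fold change 1.22 ± 0.15, SE) and K02E7.6 (0.77 ± 0.10, SE) had an adjusted p of 0.0326 in the edgeR quasi-likelihood test, and every DR library lay above every AL library for each. No gene passed in the other direction in that test, and 1597 genes had an unadjusted p under 0.05, 802 of them higher and 795 lower in DR progeny, where 743 would be expected by chance. By DESeq2 16 genes were higher and 25 lower, by the edgeR exact test 10 and 14, and by limma-voom 0 and 0. The groups did not overlap for 1762 genes, 11.9% of those tested, where chance gives 5.71% on average over all splits of the libraries. Where genes vary together, the share in a single split can lie far from that average. The share was not computed for the other splits, so chance is not excluded for it. The names of the deposited files carry 2 prefixes, shared by AL A and DR A, B and C on the one side and by AL B, AL C and DR D on the other. Within these the log2 fold change of amt-1 was 0.98 and 1.63, and that of K02E7.6 was 0.84 and 0.83. The gene amt-1 overlaps C05E11.15, a non-coding RNA on the opposite strand. Where they overlap, reads of the 2 genes cannot be told apart, because the libraries were not strand-specific. Whether HTSeq set such reads aside or counted them for amt-1, and how long the overlap is, was not checked. Neither gene passed without AL A (adjusted p of 0.161 for amt-1 and 0.272 for K02E7.6), without AL B (0.352 and 0.285), without AL C (0.363 for both) or without DR A (0.146 for both), and K02E7.6 also missed the threshold without DR B (0.159). The log2 fold changes with 1 library left out stayed at 1.1 to 1.3 for amt-1 and 0.72 to 0.82 for K02E7.6. With the rRNA share of each library as a covariate both had an adjusted p of 0.151 (log2 fold changes 0.99 and 0.67), without both DR C and DR D 0.0639 (1.15 and 0.75), and by limma-voom 0.119 for amt-1 and 0.0889 for K02E7.6.

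**Figure D1:**
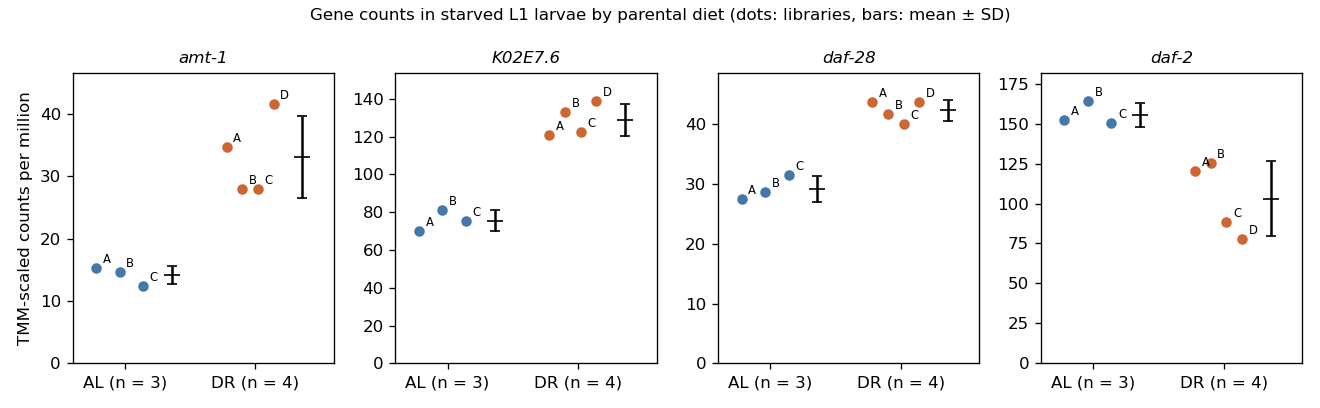
TMM-scaled CPM of amt-1, K02E7.6, daf-28 and daf-2 in each AL (blue) and DR (orange) library, with the mean and SD of the group beside the points; each panel starts at 0. All DR libraries lie above all AL libraries for amt-1, K02E7.6 and daf-28 and below them for daf-2, and of these genes amt-1 and K02E7.6 passed the test over all genes.

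The genes with the next smallest p did not pass over all genes and are given as values. Among those with more RNA in DR progeny was daf-28, an insulin-like peptide gene expressed in sensory neurons that favours growth over dauer arrest, at 29.2 ± 2.12 CPM in AL and 42.3 ± 1.80 CPM in DR progeny (log2 fold change 0.54, adjusted p = 0.193, edgeR). The caenacin gene cnc-8, of an antimicrobial peptide family, stood at 57.8 and 77.6 CPM, and W06H8.2 at 13 and 23.1 CPM. W10G11.3 (24.0 and 38.4 CPM) and the C-type lectin gene clec-210 (0.120 and 1.22 CPM, the first below the level that a count of 0 allows) share their locus with lgc-45 and srt-56 on the opposite strand, and R05H11.2 (13.7 and 19.9 CPM) with a non-coding RNA. The gene srlf-37 stood at 1.32 and 3.33 CPM. Among those with less RNA in DR progeny, the nuclear export receptor gene xpo-1 had 278 CPM in AL and 189 CPM in DR progeny, and it overlaps ZK742.3, ZK742.4 and ZK742.6 on the opposite strand. The ubiquitin ligase gene siah-1 had 102 and 74.0 CPM, F47B8.8 had 38.2 and 25 CPM, the C-type lectin gene clec-75 had 14.9 and 9.42 CPM, and C29F3.7 had 11.7 and 5.96 CPM. The infection response gene irg-2 had 1.85 and 0.532 CPM. The adjusted p of these genes lay between 0.193 and 0.371.

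Of 40 insulin-like peptide genes 21 were expressed enough to be tested, and 17 of these had more RNA in DR progeny. The list was called higher by camera (adjusted p = 3.40e-05; adjusted p = 0.267 with an estimated correlation). No member passed over all genes, and 4 rose when adjusted over the list alone: daf-28 (adjusted p = 0.00136, edgeR), ins-4 (0.0170, from 4.78 to 7.71 CPM), ins-26 (0.0196, from 24.4 to 36.6 CPM) and ins-6 (0.0237, from 11.1 to 16 CPM). The products of daf-28, ins-4 and ins-6 are known as agonists of the insulin receptor DAF-2. The median of the list was 0.19 and 0.35 within the file-name prefixes, 0.17 without AL B, 0.42 without AL C, 0.16 without DR C, 0.12 without both DR C and DR D, and 0.18 with each library's transcript length trend removed. The peptide gene ins-7 had 12 counts over all libraries and was not tested.

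Neuropeptide genes, whose products modulate neurons and muscle, were called higher as a list (adjusted p = 1.59e-08, camera; adjusted p = 0.758 with an estimated correlation). Of 97 tested members 77 had more and 20 had less RNA in DR progeny, and none passed alone. The FMRFamide-like peptide gene flp-28 had 78.2 ± 15.4 CPM in AL and 118 ± 19.7 CPM in DR progeny, flp-18 had 195 and 271 CPM, and flp-21 had 86.9 and 111 CPM, while flp-10 had a log2 fold change of −0.36. The list's median was 0.18 and 0.20 within the prefixes, 0.10 without both DR C and DR D, and 0.12 with the transcript length trend of each library removed. Pan-neuronal markers, such as synaptic vesicle genes, had a median of 0.01 over 31 genes and were not called (adjusted p = 0.527). The mean list score of the neuropeptides was highest in DR C (0.232) and lowest in AL B (−0.244), and that of AL C (0.038) lay above that of DR B (−0.040).

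**Figure D2:**
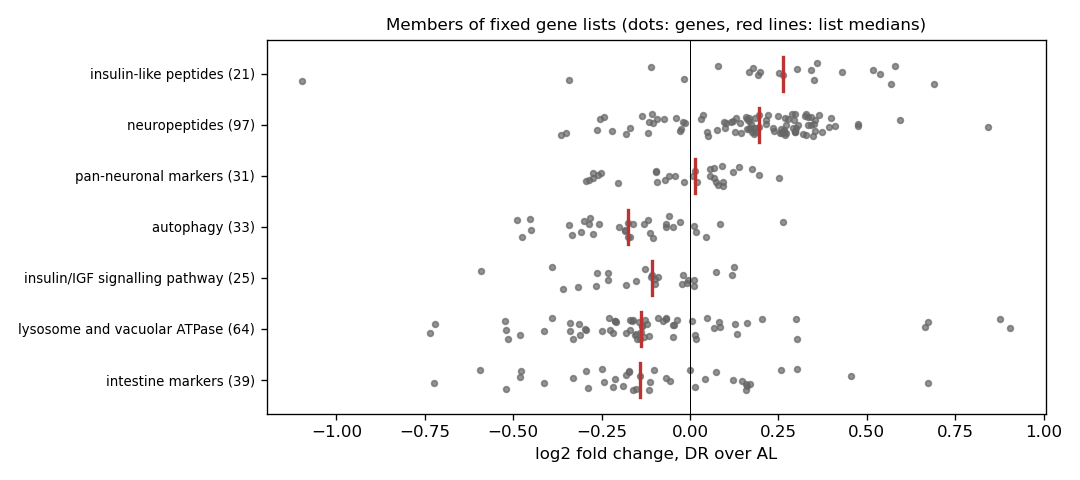
Log2 fold change, DR over AL, of every tested member of 7 fixed gene lists (grey dots, number of genes in brackets), with the median of each list as a red line. The medians are 0.26 for the insulin-like peptides, 0.19 for the neuropeptides, 0.01 for the pan-neuronal markers, −0.17 for autophagy, −0.11 for the insulin/IGF signalling pathway and −0.14 both for the lysosome and vacuolar ATPase and for the intestine markers; no dot passed the test over all genes.

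Autophagy genes, which serve the recycling of cell contents during starvation, were called lower as a list (adjusted p = 7.88e-07, camera; adjusted p = 0.267 with an estimated correlation). Of 33 tested members 28 had less RNA in DR progeny and none passed alone. The autophagosome maturation gene epg-5 had a log2 fold change of −0.45, the mitophagy receptor gene dct-1 of −0.47, the Atg8 homologue lgg-2 of −0.34 (485 and 382 CPM) and the receptor gene sqst-1 of −0.33. The other Atg8 homologue lgg-1 stood at 669 ± 7.92 and 599 ± 47 CPM, and the parkin gene pdr-1 went the other way at 0.26. The median was −0.14 and −0.22 within the prefixes, and −0.10 with the rRNA share as a covariate. Lysosome and vacuolar ATPase genes were called lower as well (adjusted p = 1.85e-04; adjusted p = 0.448 with an estimated correlation), with 47 of 64 members lower and none past the test. Examples are the proton pump subunit genes vha-5 (−0.31) and vha-12 (−0.23) and the aspartyl protease genes asp-5 (−0.48) and asp-6 (−0.33). The list shares 12 members with the intestine markers, asp-5 and asp-6 among them, and its other 52 members had a median of −0.14. The 27 intestine markers outside the lysosome list had a median of −0.10, with 16 of them lower. The median of this list was −0.14 and −0.18 within the prefixes, and −0.07 with the rRNA share as a covariate. In DR D, the library with the lowest autophagy score (−0.224), rRNA took 22.5% of the counts, against 11% to 12% in the other DR libraries and 7.54% to 11.8% in AL libraries.

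Food and insulin-like peptides act on growth, arrest and lifespan through the insulin/IGF signalling pathway. Its gene list was called lower (adjusted p = 0.00183, camera, and 0.267 with an estimated correlation), with 20 of 25 members lower and none past the test. The list also holds genes that the pathway restrains, such as daf-16, and genes of other nutrient pathways, such as the TOR genes daf-15 and rsks-1. Less RNA from such a mix does not show that signalling was lower. The insulin receptor gene daf-2 had 155 ± 7.35 CPM in AL and 103 ± 23.3 CPM in DR progeny (log2 fold change −0.59 ± 0.15, SE, adjusted p = 0.371, edgeR), with −0.45 and −1.0 within the prefixes, and it overlaps the non-coding linc-143 on the same strand. The kinase genes akt-1 (−0.32) and rsks-1 (−0.39) and the raptor gene daf-15 (−0.26) had less RNA too. The FoxO transcription factor gene daf-16, at 305 ± 16.7 and 308 ± 39.5 CPM, overlaps 6 non-coding RNAs on the opposite strand and differed by less than its spread. The list's median was −0.18 and −0.05 within the prefixes, the second of these not past the test (adjusted p = 0.0918), −0.07 without AL A, and −0.06 with the transcript length trend removed. Genes that DAF-16 activates were not called (12 higher, 19 lower, adjusted p = 0.166). Among them the superoxide dismutase gene sod-3 had 8.60 ± 3.37 and 7.83 ± 2.19 CPM (it overlaps C08A9.3 and lido-1 on the opposite strand), the metallothionein gene mtl-1 had 159 ± 14.9 and 141 ± 22.3 CPM, and the small heat shock protein gene hsp-12.6 had 46.2 ± 18.8 and 39.5 ± 17.3 CPM. Within prefix 1, where AL A is the only AL library, the sign of sod-3, mtl-1 and hsp-12.6 turned, to log2 fold changes of 0.83, 0.06 and 0.72. Within prefix 2, where DR D is the only DR library, they were −0.99, −0.61 and −1.28. Each of these rests on 1 library and is not a comparison of the groups.

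Intestine markers, which include 12 genes of the lysosome list, were called lower (25 of 39 members, median −0.14, adjusted p = 0.0169, camera; adjusted p = 0.267 with an estimated correlation), and this was the list that the set test fry also called (adjusted p = 0.0257). The intestinal filament gene ifb-2 had 1625 CPM in AL and 1330 CPM in DR progeny, asp-5 had 1361 and 974 CPM, asp-6 had 4987 and 3965 CPM, and dct-16 had a log2 fold change of 0.45. The call was absent without AL A (median −0.14, adjusted p = 0.0778) and within prefix 2 (−0.10, adjusted p = 0.167, against −0.18 within prefix 1), and the median was −0.08 without DR A and −0.09 without DR C. Genes of the glyoxylate cycle, gluconeogenesis and trehalose were called lower (13 of 18 members, median −0.14, adjusted p = 0.00770, camera, and 0.267 with an estimated correlation). The list also holds genes that break down trehalose and glycogen. Less RNA from such a mix does not show that less sugar was made from stored fat. The glycogen debranching enzyme gene agl-1 had a log2 fold change of −0.35, the trehalase gene tre-5 of −0.70 and the PEP carboxykinase gene pck-2 of −0.36. This call was absent without AL A (median −0.07, adjusted p = 0.171), within prefix 2 (−0.10, adjusted p = 0.421, against −0.22 within prefix 1), and with each library's transcript length trend removed (−0.09, adjusted p = 0.0887). The glyoxylate cycle gene icl-1 had 249 ± 163 CPM in AL and 161 ± 35 CPM in DR progeny, and AL A alone stood at 437 CPM. Without AL A its log2 fold change went from −0.63 to 0.05. For each of the lists of autophagy, insulin/IGF signalling, intestine and glyoxylate genes, the AL and DR libraries did not overlap in their mean list score (exact permutation p = 0.0286, the smallest that 35 splits can give, and 0.286 after Benjamini-Hochberg adjustment over 40 lists). The F-box protein score did not overlap either (exact permutation p = 0.0571). For the insulin-like peptides and the lysosome the exact p was 0.0857, and for the neuropeptides it was 0.171.

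**Figure D3:**
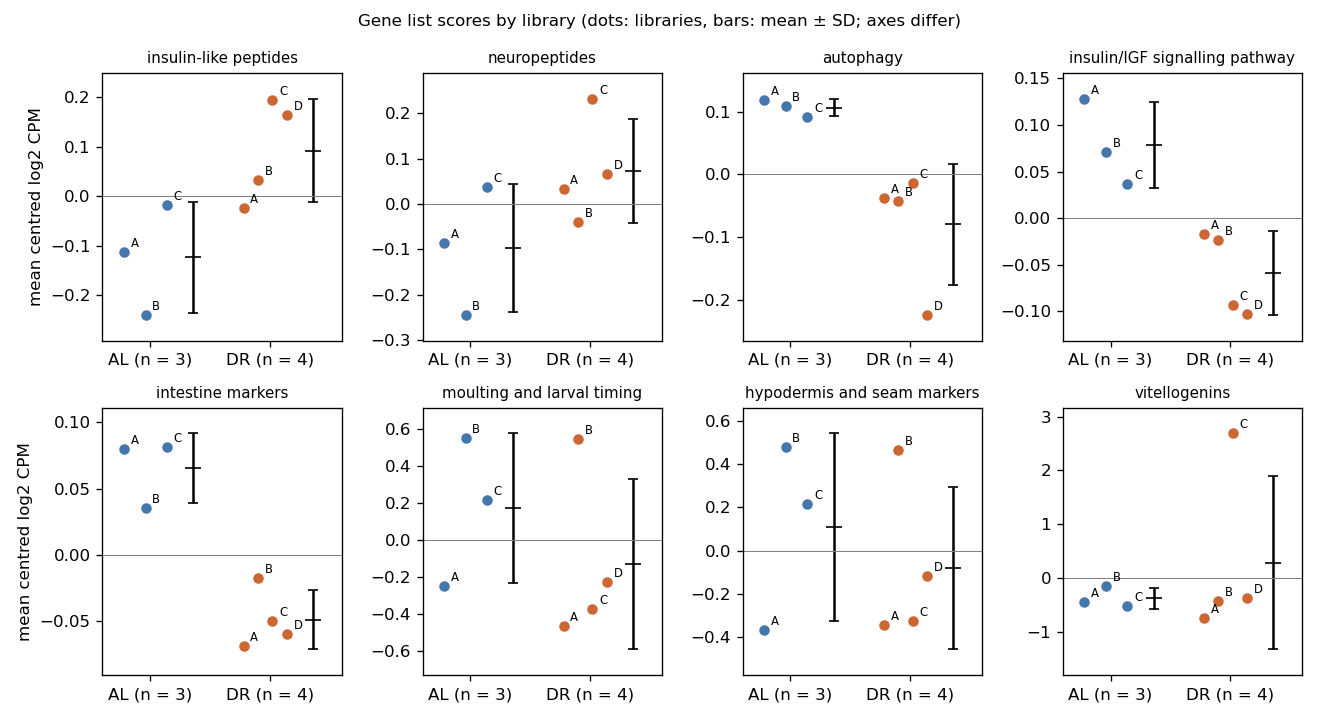
Mean centred log2 CPM over the members of 8 fixed gene lists in each AL (blue) and DR (orange) library, with the mean and SD of each group; the vertical axes differ between panels. The groups do not overlap for autophagy, the insulin/IGF signalling pathway and the intestine markers; DR B lies with AL B for moulting and hypodermis genes, and DR C stands apart for the vitellogenins at 2.69.

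Moulting and larval timing genes were called lower (28 of 32 members, median −0.21, adjusted p = 0.00405, camera; adjusted p = 0.844 with an estimated correlation). The call was absent without AL B (median −0.05, adjusted p = 0.132), within prefix 1 (−0.003, adjusted p = 0.843, against −0.46 within prefix 2) and without both DR C and DR D (−0.04, adjusted p = 0.188). Their mean score was high in AL B (0.553), AL C (0.217) and DR B (0.546) and between −0.462 and −0.229 in the other 4 libraries. Heat shock and unfolded protein response genes were called lower (29 of 44 members, median −0.10, adjusted p = 0.00605; adjusted p = 0.375 with an estimated correlation). Among them were the ER stress kinase gene pek-1 (−0.31) and the ER chaperone gene enpl-1 (−0.32), while the mitochondrial chaperone gene hsp-60 stood at 0.42. That call was absent without AL B (−0.07, adjusted p = 0.0678), without both DR C and DR D (−0.06, adjusted p = 0.0640), with a stricter filter on low counts (−0.05, adjusted p = 0.0997) and within prefix 1 (0.003, adjusted p = 0.725, against −0.17 within prefix 2), and the median was −0.06 without DR D. Pharyngeal muscle markers were called higher (15 of 18 members, median 0.14, adjusted p = 0.0169; adjusted p = 0.844 with an estimated correlation), and the pharyngeal homeobox gene ceh-22 rose when adjusted over the list alone (adjusted p = 0.0373, edgeR; from 11.1 to 15.8 CPM). This call was absent without AL A (0.15, adjusted p = 0.0866), without AL B (0.03, adjusted p = 0.505), without both DR C and DR D (0.08, adjusted p = 0.147) and within prefix 1 (0.11, adjusted p = 0.151, against 0.26 within prefix 2), and the median was 0.21 with the transcript length trend removed.

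F-box protein genes were called lower (118 of 191 tested members, median −0.11, adjusted p = 0.0395, camera; adjusted p = 0.548 with an estimated correlation). The call was absent in 16 of 26 alternatives. Those include the fits without AL A (median −0.09), AL B (−0.10), DR A (−0.12), DR B (−0.11) or DR D (−0.07), with adjusted p between 0.0586 and 0.103, and both prefixes (−0.06 and −0.17). Early zygotic embryo transcripts were called lower (8 of 9 tested members, median −0.26, adjusted p = 0.0395; adjusted p = 0.844 with an estimated correlation), and the call was absent in 12 of 26 alternatives. Without AL B their median was −0.001 (adjusted p = 0.850), without DR A −0.22, without DR C −0.21, without DR D −0.16, and within the prefixes 0.10 and −0.59, while without AL A it was −0.54 and without AL C −0.48. Leaving out AL B lowered the number of called lists from 12 to 8, the lowest of the 7 such fits, and the highest was 16.

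Yolk genes were not called in the test as planned. The 6 vitellogenin genes, normally expressed in the adult intestine, all had positive log2 fold changes (median 1.3, adjusted p = 0.0801, camera) that rested on DR C. There vit-2 had 290 CPM and vit-6 284 CPM, against 37.2 to 57.9 and 32.7 to 51.1 CPM in the other 6 libraries. The gene vit-2 overlaps C42D8.9 on the opposite strand. The groups' means were 46.8 ± 9.59 and 103 ± 125 CPM for vit-2 and 44.1 ± 6.59 and 97.4 ± 124 CPM for vit-6. Without DR C the log2 fold change went from 1.14 to −0.21 for vit-2 and from 1.15 to −0.32 for vit-6. With the transcript length trend removed and DR C included, the list was called higher (median 1.5, adjusted p = 0.0464; adjusted p = 0.810 with an estimated correlation). The acyl-CoA synthetase gene acs-2 had 15.4 ± 16.7 and 9.57 ± 6.51 CPM, with 34.6 CPM in AL A, and without AL A its log2 fold change went from −0.72 to 0.73. Within the prefixes it was −2.42 and 1.73, values that rest on AL A and on DR D (18.8 CPM) as the only library of their group. The desaturase gene fat-7 had 0 counts in all libraries. Genes of lipolysis and fatty acid oxidation (adjusted p = 0.714), fatty acid synthesis (0.658), glycolysis (0.269), the nuclear-encoded respiratory chain (0.714), oxidative stress defence (0.562) and xenobiotic metabolism (0.411) were not called either.

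Cytosolic ribosomal protein genes (61 of 81 higher, median 0.03, adjusted p = 0.504, camera), translation factors (adjusted p = 0.549) and proteasome genes (29 of 35 higher, adjusted p = 0.105) were not called. Nor were cell cycle and DNA replication genes (31 of 48 higher, adjusted p = 0.0554), histones (0.355), chromatin modifiers (0.527), P granule and small RNA genes (0.287), oocyte and early embryo transcripts (0.269) and sperm transcripts (0.411, 5 genes). With the transcript length trend of each library removed, camera called cell cycle genes higher (median 0.09, adjusted p = 0.00747; adjusted p = 0.729 with an estimated correlation). It then called histones lower (−0.13, adjusted p = 0.0379; adjusted p = 0.810 with an estimated correlation) and ribosomal protein genes lower, their median turning from 0.03 to −0.05 (adjusted p = 0.0464; adjusted p = 0.849 with an estimated correlation). Hedgehog-related genes (37 of 59 lower, adjusted p = 0.0554), hypodermis and seam markers (0.339), collagens (0.503), body wall muscle markers (0.714), dauer and TGF-beta pathway genes (0.714) and nuclear hormone receptors (0.986) did not pass, nor did chemoreceptor genes (289 of 490 higher, adjusted p = 0.105). C-type lectins (adjusted p = 0.83) and antimicrobial effectors (0.961) went both ways. When adjusted over the list alone clec-210 rose and clec-75 and clec-72 fell (adjusted p = 0.0254, 0.0254 and 0.0420, edgeR), and among the effectors cnc-8 and abf-6 rose and irg-2 fell (adjusted p = 0.0147, 0.0247 and 0.0120, edgeR). For 8 of the 28 lists that were not called the median, the mean and the test differed in sign, and for no called list.

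Of the 12 mitochondrially encoded genes on the list 8 were matched to a feature, and the share given here covers these 8 only. They took 0.843% ± 0.0408 (SD, n = 3) of the counts in AL and 0.799% ± 0.0624 (SD, n = 4) in DR progeny (two-sided exact permutation p = 0.314). As a list 7 of 8 were lower without a call (median −0.11, adjusted p = 0.105, camera). With the transcript length trend removed the list was called lower (median −0.19, adjusted p = 0.0168; adjusted p = 0.729 with an estimated correlation). The share of rRNA was 9.43% ± 2.19 in AL and 14.3% ± 5.47 in DR progeny (exact permutation p = 0.257; smallest possible 0.0286).

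The authors' deposited comparison of the same libraries lists 13436 genes, with 38 at an adjusted p under 0.05, 13 higher and 25 lower in DR progeny. Across genes its log2 fold changes differed from those given here by a median of 0.00155. All 38 had an unadjusted p under 0.05 in the edgeR quasi-likelihood test, and amt-1 and K02E7.6 passed it after adjustment. The groups did not overlap for 32 of the 38, and 27 were among the 41 calls of DESeq2. The steps of the submitters' notes, run again here, called 20 genes, 17 of them among the 38. By the authors' values the lysozyme gene ilys-5 had a log2 fold change of 2.14, amt-1 of 1.23, daf-28 of 0.54 (adjusted p = 0.0138 in their edgeR test) and daf-2 of −0.59 (0.0588). For 4 of the 38 genes, Y47H9C.1, Y38E10A.14, Y58A7A.3 and C50F7.5, AL B lay more than 1 log2 unit from all other libraries.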

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

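The tests of shared paralog reads, of the neuron share and of the rRNA share were chosen only after the results were seen, and that of the length trend after the data were seen. Of 73 values looked at in the 4 DR libraries, 10 had a library far from the others, where chance gives about 1 in 20, or 3.65. The values are not independent. Those of vit-2, vit-6 and the vitellogenin list share 1 excess in DR C, and rRNA is among the 10 most abundant features in DR D. The 2 counts therefore do not measure an excess of outliers.

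The vitellogenin score of DR C was 2.69, against −0.747 to −0.372 in the other DR libraries, with 290 CPM of vit-2 and 284 CPM of vit-6. Reads shared between paralogs are argued against as a cause, since vit-6, whose sequence differs most from the others, stood at 7.15 times the mean of the other 6 libraries. Material of mothers or unhatched embryos carried into DR C may account for it, and it stays open: the oocyte and early embryo score of DR C lay 0.322 log2 units above the highest other library, outside their range but by less than that range. The eggshell genes perm-2 and perm-4 stood there at 6.51 and 6.04 times the other libraries' mean, the eggshell gene cpg-2 at 4.29 and the yolk receptor gene rme-2 at 1.77, and 16 of 35 members of the oocyte list were highest in DR C. A difference between the parents of this replicate is open and untested.

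Neuropeptide genes were higher and autophagy genes lower as lists in DR progeny by camera (adjusted p = 0.758 and 0.267 with an estimated correlation). The pan-neuronal markers gave no sign of a larger share of RNA from neurons in DR libraries. Their median log2 fold change was 0.0148 (95% bootstrap interval −0.070 to 0.067) against 0.19 for the neuropeptides. That interval covers the spread between markers and not between libraries. Neuropeptide transcripts were also shorter (median 591 bp against 2002 bp), and with the length trend removed the medians were 0.118 and 0.046. A larger neuron share is thus not excluded. Both lists stayed called by camera with a length trend removed and with the rRNA share as a covariate. With the trend removed the neuropeptide median was 0.118 and the autophagy median −0.16. With the rRNA share as a covariate they were 0.216 and −0.10. Neither list passed with an estimated correlation where the trend was removed (adjusted p = 0.729 and 0.330). Camera at the preset correlation called lists in every split of the libraries. The calls that stayed therefore do not exclude either as the whole cause. Log2 fold changes did fall with transcript length across genes (Spearman rho −0.199; genes are not independent replicates), with medians of 0.07 in the shortest of 4 length classes and −0.05 in the longest. The parents' diet, chance and, for autophagy, a smaller share of RNA from the intestine (marker median −0.14, or −0.10 outside the lysosome list) may each account for what remains, and stay open.

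The number of genes past the test does not exclude chance: 4 of the 35 splits of the libraries gave at least the 2 genes of the real split, and the highest other split gave 54. That split sets AL B, AL C and DR B against the rest, which points to a structure of the samples that the groups do not follow. With 1597 genes at an unadjusted p under 0.05 the real split was exceeded by 1 other, with 1611, so that 2 of 35 were as large and chance is not excluded. For called lists, 24 of 35 splits gave at least 12 and the highest other gave 20, so chance is not excluded for their number either. The smallest unadjusted list p of the real split was 3.98e-10 (camera, preset correlation), that of the neuropeptides. Most other splits gave a smaller one, down to 2.05e-32 with AL A, AL C and DR C against the rest. Chance is therefore not excluded for the size of these p-values.

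The autophagy score of DR D was −0.224, against −0.043 to −0.014 in the other DR libraries. The nuclear hormone receptor score of DR C was 0.111, against −0.027 to −0.007. In DR D rRNA took 22.5% of the counts, against 11% to 12%, and the 10 most abundant features took 28.2%, against 17.1% to 18.6%. The gene srlf-37 had 4.47 CPM in DR D, against 2.94 to 2.97. In DR B 20940 features had at least 1 read, against 20094 to 20143. Reads that HTSeq could not assign to a single feature made up 4.81% in DR D, against 3.73% to 3.83% in the other DR libraries. This share, which no comparison of the deposited tables uses, was 0.546 percentage points higher in DR than in AL libraries without overlap (exact permutation p = 0.0857, and 0.471 after Benjamini-Hochberg adjustment over 11 measures). The share of unaligned reads did not overlap either, at 17.3% to 18.1% in AL and 15.2% to 17.1% in DR libraries (DR minus AL −1.14 percentage points), with the same exact permutation p.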

How the results depend on the processing

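The fits with the rRNA share, without both DR C and DR D, without rRNA features, with the length trend removed and with the submitters' steps were chosen only after the data were seen. The counts of genes higher and lower in DR progeny (2 and 0) became 1 and 0 with library size only, 27 and 50 with no filter, 0 and 0 without robust estimation or by limma-voom, 16 and 25 by DESeq2, 10 and 14 by the edgeR exact test, 9 and 11 by the submitters' steps, 2 and 2 with the replicate letters as a block, 0 and 0 within prefix 1, 191 and 425 within prefix 2, 0 and 1 with the rRNA share and 0 and 0 without both DR C and DR D. Leaving out 1 library at a time gave 0 to 2 higher and 0 lower. Within a prefix fewer samples enter and 1 group has a single library; otherwise the cause was not tested. The 12 called lists became 0 with an estimated correlation and 1 by fry, which asks another question, and lay between 8 and 16 with 1 library left out. They became 16 with the length trend removed (11 of the 12 kept), 17 with the rRNA share (11 kept), 17 within prefix 1 (7 kept) and 18 within prefix 2 (8 kept). The share of the 8 matched mitochondrially encoded genes differed by −0.045 points and by 0.0022 with the 10 most abundant features left out of the total. Those features took a mean of 15.9% of the counts in AL and 20.5% in DR libraries. Since only the total differs between these values, the change of sign comes from that share. Whether the replicate letters pair the libraries is not settled. Same-letter correlations of deviations from the group means were 0.197, 0.268 and −0.101 for A, B and C. AL B correlated best with DR B, while AL A correlated best with DR C (0.233) and AL C with DR B (0.253).

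Of 666 gene values under the alternatives 560 kept direction and side of the threshold, 56 passed it newly, 20 no longer did and 30 turned sign; of 312 list values 249 kept both and 63 lost the call. Log2 fold changes of amt-1 lay between 0.98 and 1.63 and of K02E7.6 between 0.67 and 0.84, with the call kept in 18 and 16 of 27 alternatives. Neither amt-1 nor K02E7.6 turned sign; the cause was not tested for the genes that did, except where fewer samples enter. Within prefix 1, where AL A is the only AL library, mtl-1 went to 0.0649, hsp-12.6 to 0.72, sod-3 to 0.83 and daf-16 to −0.0863. Within prefix 2 icl-1 went to 0.0287, vit-2 to −0.16, vit-6 to −0.22 and acs-2 to 1.73, the last at an adjusted p of 0.00437 (edgeR) that rests on DR D as the only DR library, while hsp-12.6 (−1.28), mtl-1 (−0.61) and sod-3 (−0.99) kept their sign. Without both DR C and DR D vit-2 went to −0.27, vit-6 to −0.42, hsp-12.6 to 0.0496, sod-3 to 0.15 and daf-16 to −0.0122. With the rRNA share hsp-12.6 went to 0.0842, sod-3 to 0.0248 and daf-16 to −0.0833. With the replicate letters as a block sod-3 went to 0.0769 and daf-16 to −0.0662. With library size only daf-16 went to −0.0297, and with no filter to −0.0015. With 1 library left out the range was −0.90 to 0.0523 for icl-1, −0.21 to 1.42 for vit-2, −0.32 to 1.44 for vit-6, −1.26 to 0.73 for acs-2, −0.54 to 0.11 for hsp-12.6, −0.41 to 0.15 for sod-3 and −0.0626 to 0.0701 for daf-16. Depth limits genes near the floor of 0.131 to 0.180 CPM, such as clec-210 and irg-2.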

Other observations

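No test of a cause was run for the values in this part, all chosen after the data were seen. Some cuticle collagen genes were high in libraries of both groups. The cuticle collagen gene dpy-17 had 47.8 CPM in AL B, 20.7 in AL C and 51.2 in DR B, and 1.55 to 5.71 CPM in the other 4 libraries. The collagen gene sqt-3 had 46.1, 27.4 and 41.2 CPM in AL B, AL C and DR B, and 3.15 to 12.0 CPM in the others. The collagen gene dpy-7 had 5.90, 2.02 and 7.36 CPM in these libraries, and 0.365 to 0.532 CPM in the others. Other members of the collagen and moulting lists went differently: col-101 was highest in DR A, at 46.6 CPM against 11.7 to 23 CPM elsewhere, and mlt-10 had 5.66 to 9.38 CPM in AL and 8.67 to 12 CPM in DR libraries. Scores of the hypodermis and seam markers were 0.477, 0.216 and 0.462 in AL B, AL C and DR B, and −0.370 to −0.117 in the others. The first principal component, with 33.1% of the variance, placed AL B (40.0), AL C (21.3) and DR B (14.5) on the positive side and AL A, DR A, DR C and DR D between −26.3 and −9.34.

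AL B stood alone for 59 genes at more than 1 log2 unit above, and 45 genes below, all other libraries. Among these were Y38E10A.14, at 31.8 CPM against 0.365 to 2.59 elsewhere, and the asparagine synthetase gene asns-2, at 89.2 CPM against 4.45 to 24.6. The small heat shock protein gene hsp-16.11 had 14.6 CPM in AL B and 9.12 CPM in AL C, and 0.887 to 3.48 CPM in the other 5 libraries. DR D stood below all other libraries for 61 genes and DR A for 69.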
